A study of Mus musculus with 6 samples.

How the data were processed

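Total RNA was extracted with Trizol from mononuclear cells of the skeletal muscle of 6 male LLC tumour-bearing mice, and libraries were made with the SureSelect strand-specific kit. The labels give 1 factor, the genotype, with 3 mice per group (Pax7-CreERT and control). The labels give no batch, date or tumour size, and the replicate numbers follow the order of the records and pair no mice. The sample titles are numbers without a stated meaning, and that of control replicate 3 lies outside the run of the other libraries. The deposited values are CPM, the reads of a gene per 1000000 reads that the authors assigned to 17030 genes, with 0.0001 added to every value. This was read from the values themselves, since each library sums to 1000000 plus the total of the added constant. The submitters' notes name Partek, DESeq2 and the genome build mm10 and do not say what each was used for. The aligner, the counting rule and the annotation release are not stated. Gene symbols and positions are those of the deposited table, where 17009 symbols matched the RefSeq table of the same build. In that match 11201 starts were equal and 11050 ends were 1 base past the RefSeq end, so 1 was subtracted from each end. The table holds 5 genes of the Y chromosome and 0 mitochondrial genes, and its least abundant gene reaches a maximum of 0.315 CPM.

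The depth of each library was estimated from the smallest step between its low values, which is the CPM of 1 read. The libraries held an estimated 4054000 to 13360000 assigned reads, so that 1 CPM was 4.05 to 13.4 reads and carried a counting SD of 27.4% to 49.7%. Of the values of up to 20 reads, 92.9% to 94.0% were whole numbers of reads within 0.05 read. The rest held fractions, as where reads are divided between genes. Whole reads were therefore not recovered, since 95% was required. Of the genes that reach 1 CPM, 39 share identical values with another gene. Counting errors cover sampling of reads only.

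Groups were compared with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), using moderated statistics with a mean-variance trend, for the 14763 genes with at least 1 CPM in at least 3 of the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method, and genes passed at an adjusted p under 0.05. The constant of 1 shrinks the fold changes of genes near 1 CPM. Means and SDs are of CPM over the 3 mice of a group, and fold changes are Pax7-CreERT minus control on the log2 scale. Exact 2-sided permutation tests were run on single genes. The test was tried on 5 simulated data sets of 14763 genes with 200 changed genes at the spread and depth of these libraries. It recovered 87.4% of 2-fold and 99.2% of 4-fold changes, all with the right sign, with a mean of 14.8 false calls per simulation. The changed genes were drawn from those at or above the median level, and no outlying library was simulated. Recovery of fainter genes, or with fewer changed genes, was not simulated. A simulated list of 24 genes shifted by 0.8 was called in 5 of 5 simulations, and 0 of 95 unshifted lists were called. The simulated genes varied independently and the lists were random. The simulation therefore cannot show how often real lists, whose genes vary together, are called falsely.

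Gene lists were tested with limma's camera, which compares the members of a list with all other tested genes, with a preset correlation of 0.01 between genes and adjustment over 32 lists. Camera with a correlation estimated from the data, and fry, which tests whether a list's members move without comparing them with other genes, were run beside it. The estimate rests on few libraries, and the preset value can be too small for genes that vary together, so both are given. The 33 lists were NF-kB target genes, NF-kB pathway components, chemokines, inflammatory cytokines and receptors, satellite cell markers, myogenic commitment and differentiation, mature myofibre genes, macrophage, tissue-resident macrophage and inflammatory monocyte markers, reparative macrophage genes, neutrophil, T and NK cell, and B cell markers, dendritic cell and MHC class II genes, mast cell and eosinophil markers, fibro-adipogenic progenitor markers, extracellular matrix and fibrosis genes, endothelial, pericyte and smooth muscle, Schwann cell and neural, tenocyte and adipocyte markers, erythroid genes, interferon response, cell cycle, muscle atrophy and cachexia, acute phase and IL-6 to STAT3, complement, immediate early and dissociation stress, hypoxia and glycolysis, mitochondrially encoded, and nuclear oxidative phosphorylation genes. The mitochondrially encoded list had 0 members in the table and was not tested. The tested lists held 548 different genes, some of them in more than 1 list. Each list also gives the number of members that pass when adjusted over the list alone. That adjustment does not cover the number of lists, and members that vary together are not separate observations. The position of a list in each library is the median over its members of log2(CPM + 1) minus the gene's mean over the 6 libraries, called the centred log2 scale.

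The tests, the lists, the rule for naming genes and the first set of alternative analyses were set before the data were examined. The rule names Ikbkb and Pax7, then up to 10 genes per direction that pass, do not overlap between groups and lie above the median level of tested genes (18.3 CPM), leaving out clone and model names. Where a direction has fewer than 5 such genes, those with the smallest p are added until there are 5 and are described as not passing. For each list, up to 4 members with the smallest p are candidates for naming. That set held another constant on the log scale (0.25 and 5), no filter and a filter at 50 CPM, TMM factors, quantile normalization, array weights, leaving out each library in turn, an adjusted p under 0.10, an estimated correlation, fry, and leaving out members shared between lists. Chosen after the data were seen were limma voom on the estimated reads, a filter at 10 CPM, removal of the erythroid list with rescaling of the libraries, leaving out Pax7-CreERT replicate 1 and control replicate 3 together, and keeping 1 of each set of haemoglobin genes that share a locus. The 10 ways to divide the 6 libraries into groups of 3 were each tested. Figures were drawn with matplotlib 3.10.9 from tables made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.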

Results

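RNA was sequenced from mononuclear cells isolated from the skeletal muscle of 6 male C57BL/B6 mice bearing Lewis lung carcinoma (LLC), a transplantable mouse tumour used as a model of cancer cachexia. Every mouse carried floxed alleles of IKKb, the kinase that activates canonical NF-kB signalling and is encoded by Ikbkb. In 3 mice, called Pax7-CreERT here, a tamoxifen-activated Cre recombinase was expressed under the control of Pax7, the transcription factor that marks muscle satellite cells. The other 3 mice, the controls, had no Cre. All 6 mice received tamoxifen from day 10 to day 14 after the tumour cells were injected. The deposited values were in CPM, the reads of a gene per 1000000 assigned reads. The depths estimated from the smallest steps between values were 9512000, 13360000 and 4913000 reads in Pax7-CreERT replicates 1, 2 and 3, and 5982000, 7423000 and 4054000 in control replicates 1, 2 and 3. At these depths the counting error of a gene at 10 CPM had an SD of 8.65% to 15.7% per library.

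The libraries were not equally alike. Control replicate 3 lay at 51.6 on the first principal component, which held 41.3% of the variance, and the other 5 libraries lay between -17.0 and 0.20. Haemoglobin transcripts made up 12.6% of its CPM, against 4.47% and 2.57% in control replicates 1 and 2 and 2.72%, 1.84% and 4.83% in the Pax7-CreERT libraries. It was also the shallowest library.

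The comparison asks how removing IKKb from Pax7-lineage cells of tumour-bearing mice alters the transcripts of the mononuclear cells in muscle. No mouse carried Cre without the floxed alleles, so effects of Cre itself and of the deletion cannot be told apart. Ikbkb itself, on chromosome 8 of mm10 at 22659205 to 22706583, was present at similar levels in every library. It measured 51.4, 48.4 and 52.7 CPM in the Pax7-CreERT replicates and 51.3, 57.4 and 48.9 CPM in the controls. The means were 50.8 ± 2.23 and 52.5 ± 4.397 CPM (SD, n = 3 each), with a log2 fold change of -0.04 (SE 0.13, 95% interval -0.33 to 0.24, adjusted p = 0.970). An exact 2-sided permutation test gave p = 0.7, where 3 mice against 3 cannot give less than 0.1. The interval corresponds to a change in the mixed cells between -20.4% and 18.3%. Gene-level values do not separate the floxed exons from the rest of the transcript, and satellite cells are only part of the preparation, so deletion in them was not measurable here. Pax7 (chromosome 4, 139738081 to 139832968) measured 14.4, 16.3 and 19.3 CPM in the Pax7-CreERT replicates and 16.6, 21.6 and 10.9 CPM in the controls. Its log2 fold change was 0.07 (SE 0.24, adjusted p = 0.976, exact permutation p = 1), and -0.02 with TMM factors.

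Among single genes, the Pax7-CreERT mice differed most clearly in Zfp697, a gene for a zinc finger protein, which fell 3.52-fold, from 65.4 ± 9.57 CPM in the controls to 18.6 ± 3.43 CPM (SD, n = 3 each). The values were 21.97, 15.1 and 18.7 CPM in the Pax7-CreERT replicates and 76.1, 62.8 and 57.5 CPM in the controls. Zfp697, at 98382481 to 98431949 on chromosome 3, had a log2 fold change of -1.77 (SE 0.17, adjusted p = 0.0231). It was the 1 gene of 14763 tested with limma that passed at an adjusted p under 0.05, and 0 genes rose. Its exact permutation p was 0.1, the smallest that 3 mice against 3 can give. At an unadjusted p under 0.05 there were 676 genes higher and 139 lower, 815 in all, where 738 were expected by chance. With TMM factors they were 373 higher and 310 lower, 683 in all, and with quantile normalization 366 higher and 314 lower. The same count was 830 from voom and 1121 with array weights. It was 443, 493 and 862 without Pax7-CreERT replicates 1, 2 and 3, and 1022, 894 and 960 without control replicates 1, 2 and 3. Over the other ways to divide the 6 libraries into groups of 3 it ran from 396 to 1052, so 815 lay within what such divisions gave. The groups did not overlap for 1620 genes, or 10.97%, and chance gives 10%. The call on Zfp697 was lost without Pax7-CreERT replicate 1 (adjusted p = 0.0519), 2 (0.154) or 3 (0.231) and without control replicate 1 (0.218) or 2 (0.1702), and it was kept without control replicate 3 (0.00867), with log2 fold changes from -1.63 to -1.89. The limma p-values of single genes measure the spread between the 3 mice of each group. The camera p-values of gene lists, given below, rest instead on the preset or estimated correlation between genes.

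Of the 5 genes named for small p-values and higher values in the Pax7-CreERT mice, 4 were heat shock genes, and none of the 5 passed the adjustment over all genes. Hspa1b, which encodes an inducible HSP70 chaperone (chromosome 17, 34956429 to 34959238), measured 1655 ± 136 CPM against 645 ± 183 CPM (log2 fold change 1.40, adjusted p = 0.308). Its near-identical neighbour Hspa1a (34969359 to 34972156) measured 1870 ± 126 against 817 ± 205 CPM (1.23, adjusted p = 0.405). The adjacent Hspa1l (34972703 to 34979228) measured 58.9 ± 5.95 against 24.4 ± 5.94 CPM (1.26, adjusted p = 0.223). Hsph1, an HSP110 co-chaperone on chromosome 5 (149616845 to 149636336), measured 37.1 ± 8.07 against 16.6 ± 2.52 CPM (1.10, adjusted p = 0.405). Col15a1, a basement membrane collagen gene on chromosome 4 (47208012 to 47313165), measured 89.3 ± 16.6 against 44.0 ± 3.65 CPM (0.99, adjusted p = 0.308). In the other direction stood Cldn15, a tight junction claudin (chromosome 5, 136967869 to 136975845), with 61.9 ± 1.78 against 103.6 ± 15.4 CPM (-0.72, adjusted p = 0.703). Bnip3, a mitophagy receptor induced by hypoxia (chromosome 7, 138890836 to 138909506), measured 79.5 ± 20.4 against 138.4 ± 3.99 CPM (-0.83). Cd59a, an inhibitor of the complement attack complex (chromosome 2, 104095801 to 104115410), measured 45.8 ± 9.33 against 87.9 ± 20.03 CPM (-0.92). Dnah3, an axonemal dynein heavy chain (chromosome 7, 119921334 to 120095297), measured 12.2 ± 2.27 against 25.0 ± 4.50 CPM (-0.98). The adjusted p of these last 3 genes was 0.891. In all 9 genes the 2 groups did not overlap, which was a condition for naming them. The exact permutation p of 0.1, the smallest possible, follows from that condition. Values of these genes are means with SD of 3 mice per group.

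**Figure D1:**
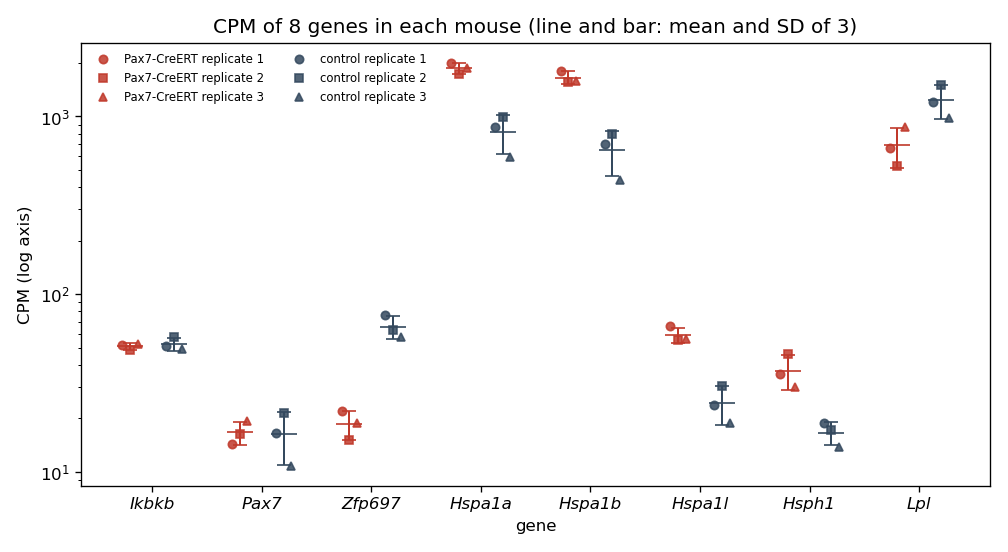
CPM of 8 genes (log axis) in each mouse of the 2 groups; points are mice, and the line and bar are the mean and SD of 3 mice. Ikbkb and Pax7 overlap between groups, Zfp697 lies at 15.1 to 21.97 CPM in the Pax7-CreERT mice and 57.5 to 76.1 CPM in the controls, and the 4 heat shock genes and Lpl do not overlap between groups without passing the adjustment over all genes.

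Genes were next read in groups fixed in advance. Of 32 lists tested, 10 differed from the other genes in the camera test with its preset correlation between genes. Mature myofibre, pericyte and smooth muscle, extracellular matrix, immediate early and interferon response genes were higher in the Pax7-CreERT mice, and erythroid, neutrophil, adipocyte, hypoxia and cell cycle genes were lower, each relative to the other tested genes. With a correlation estimated from the data, 0 of the 32 lists passed (lowest adjusted p = 0.425; 1 list had an unadjusted p under 0.05), and 0 passed with fry (lowest adjusted p = 0.367). Adjusted over the list alone or over all genes, few single members passed, as given for each group. The log2 fold change was above 0 in 68.0% of all genes, with a median of 0.09, against 0.004 and 51.0% with TMM factors, so a list whose median is below that of all genes can be lower in this test while its own median is above 0.

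Muscle structural genes were higher in the Pax7-CreERT mice as a whole list. All 24 mature myofibre genes had higher means, with a median log2 fold change of 0.82 (adjusted p = 1.35e-13, and adjusted p = 0.552 with an estimated correlation). Adjusted over the list alone 15 of them passed as higher, and over all genes 0 did. The correlation estimated between the members was 0.73, so these are not 15 separate observations. Ryr1, the calcium release channel of the sarcoplasmic reticulum, measured 42.5 ± 5.84 against 25.3 ± 4.57 CPM. Actn3, an actinin of fast fibres, measured 36.4 ± 14.4 against 16.8 ± 3.37 CPM. Tpm2, a tropomyosin, measured 250.4 ± 52.6 against 160.6 ± 23.7 CPM, and the giant filament gene Neb 81.5 ± 14.1 against 45.8 ± 15.3 CPM. The list stood highest in Pax7-CreERT replicate 1 (0.94 on the centred log2 scale) and lowest in control replicate 3 (-0.83), with the other 4 libraries between -0.29 and 0.14. Its median was 0.50 without Pax7-CreERT replicate 1 and 0.35 without both of these libraries, where the preset-correlation test still passed (adjusted p = 2.32e-05).

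The lists of satellite cell and differentiation genes did not pass with all 6 libraries and the filter used. Of 21 satellite cell markers 16 were higher and 5 lower, with a median log2 fold change of 0.05 (adjusted p = 0.614); the median was -0.03 with TMM factors, 0.11 without control replicate 2 and 0.09 without control replicate 3. Hey1, a Notch target, measured 114.0 ± 17.3 against 148.1 ± 7.54 CPM, and Notch3, a Notch receptor that mural cells also express, 282.0 ± 10.8 against 231.9 ± 42.3 CPM. The laminin receptor subunit Itga7 measured 80.0 ± 9.37 against 68.1 ± 6.07 CPM. Of 14 myogenic commitment and differentiation genes 9 were higher and 5 lower, with a median of 0.12 (adjusted p = 0.155). The commitment list passed as higher with no filter on low values (median 0.24, adjusted p = 0.0274), and its median was 0.20 without control replicate 2 and 0.19 without Pax7-CreERT replicate 3. Cdh2, the N-cadherin gene, measured 7.51 ± 0.409 against 3.97 ± 0.497 CPM. It passed as higher when adjusted over the list alone (adjusted p = 0.0457) and did not pass over all genes (adjusted p = 0.891). Des, which encodes the intermediate filament desmin, measured 203.2 ± 32.9 against 141.6 ± 16.8 CPM, and Myh8, a perinatal myosin, 3.62 ± 1.35 against 1.86 ± 0.768 CPM. This list had changes in either direction by fry's mixed test, the 1 list of 32 that did.

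Mural and matrix genes were higher with Cre. All 16 pericyte and smooth muscle markers had higher means, with a median log2 fold change of 0.31 (adjusted p = 2.24e-05, and adjusted p = 0.552 with an estimated correlation). The contractile gene Cnn1 measured 20.2 ± 3.58 against 11.2 ± 0.340 CPM. It passed as higher adjusted over the list alone (adjusted p = 0.0235), and 0 members passed over all genes. Cspg4, the NG2 proteoglycan of pericytes, measured 173.0 ± 25.9 against 123.1 ± 21.2 CPM, and the myosin light chain gene Myl9 407.3 ± 65.6 against 303.8 ± 17.7 CPM. The pericyte median was 0.20 without Pax7-CreERT replicate 2. Of 25 extracellular matrix and fibrosis genes 23 were higher and 2 lower, with a median of 0.43 (adjusted p = 8.35e-04, and adjusted p = 0.777 with an estimated correlation). The collagen VI gene Col6a2 measured 145.4 ± 52.3 against 69.1 ± 7.02 CPM. It passed as higher adjusted over the list alone (adjusted p = 0.0463), and no member passed over all genes. Col1a1 measured 130.5 ± 85.6 against 39.97 ± 10.9 CPM, and Postn, the matricellular protein periostin, 34.5 ± 8.24 against 21.0 ± 4.23 CPM. The matrix list was highest in Pax7-CreERT replicate 1 (0.75) and low in replicate 3 (-0.25), like the controls (-0.36 to -0.08); it did not pass without Pax7-CreERT replicate 1 (adjusted p = 0.0936) or control replicate 2 (adjusted p = 0.0733), and its median was 0.67 without Pax7-CreERT replicate 3.

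The other stromal lists of progenitor, tendon, nerve and endothelial genes did not pass with all 6 libraries. Among 20 markers of fibro-adipogenic progenitors, the mesenchymal cells of muscle, 13 were higher and 7 lower (median 0.12, adjusted p = 0.996). The microfibril gene Fbn1 measured 280.3 ± 138 against 131.8 ± 17.1 CPM and the proteoglycan gene Lum 75.4 ± 36.9 against 41.1 ± 7.01 CPM. The progenitor list was lower without Pax7-CreERT replicate 1 (median -0.12, adjusted p = 0.0317), and its median reached 0.32 without control replicate 3 (adjusted p = 0.0575). Of 12 tenocyte markers 11 were higher (median 0.22, adjusted p = 0.333), among them Col12a1 at 55.5 ± 23.6 against 34.4 ± 10.7 CPM. They passed as higher without control replicate 3 (adjusted p = 0.00570) or Pax7-CreERT replicate 3 (0.0199), while their median was -0.03 without Pax7-CreERT replicate 1 or control replicate 2. All 13 Schwann cell and neural markers were higher (median 0.18, adjusted p = 0.0976). The neural crest transcription factor gene Sox10 measured 23.3 ± 3.98 against 18.7 ± 2.33 CPM and the potassium channel gene Kcna1 177.6 ± 37.5 against 121.0 ± 25.4 CPM. This list passed without Pax7-CreERT replicate 1 (adjusted p = 0.0474) or 3 (0.0372), and its median was 0.058 without control replicate 3. Endothelial markers divided into 11 higher and 10 lower (median 0.01, adjusted p = 0.143), with Aplnr, the apelin receptor, at 235.8 ± 66.1 against 166.0 ± 18.8 CPM and Ly6c1 at 1755 ± 376 against 2478 ± 572 CPM. They passed as lower without Pax7-CreERT replicate 2 (median -0.06, adjusted p = 0.0497) or control replicate 3 (median -0.14, adjusted p = 0.00115), while their median was 0.15 without control replicate 2.

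Adipocyte genes were lower, 8 of 9 members with a median log2 fold change of -0.27 (adjusted p = 2.91e-04, and adjusted p = 0.425 with an estimated correlation). No member passed, over the list alone or over all genes. Cidec, a lipid droplet protein of fat cells, measured 3.08 ± 1.39 against 8.04 ± 4.67 CPM. Lipe, the hormone-sensitive lipase, measured 111.9 ± 10.1 against 136.8 ± 26.1 CPM, and the adipokine gene Adipoq 6.17 ± 1.61 against 8.71 ± 3.13 CPM. The list was highest in control replicate 3 (0.61), and the other 5 libraries lay between -0.22 and 0.11. Without Pax7-CreERT replicate 1 and control replicate 3 together the adipocyte list did not pass (median -0.20, adjusted p = 0.0927).

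The NF-kB and cytokine lists did not pass with all 6 libraries. Of 34 NF-kB target genes 27 were higher and 7 lower, with a median log2 fold change of 0.12 (adjusted p = 0.696). Ikbke, an IKK-related kinase, measured 3.85 ± 1.43 against 2.05 ± 1.01 CPM, and the NF-kB subunit gene Rel 64.9 ± 21.0 against 50.1 ± 1.53 CPM. Nos2, the inducible nitric oxide synthase, measured 11.3 ± 2.28 against 8.14 ± 3.70 CPM. The target list passed as higher without Pax7-CreERT replicate 2 (median 0.27, adjusted p = 6.29e-04), while its median was 0.008 without Pax7-CreERT replicate 1, -0.005 without Pax7-CreERT replicate 1 and control replicate 3 together, and 0.03 with TMM factors. Of 25 pathway components other than Ikbkb 16 were higher and 9 lower (median 0.03, adjusted p = 0.529). The kinase gene Irak4 measured 25.2 ± 1.65 against 22.1 ± 0.993 CPM and the TNF receptor gene Tnfrsf1b 92.1 ± 5.89 against 102.3 ± 9.54 CPM. The median of the components was 0.10 without control replicate 2 and -0.04 without control replicate 3. Chemokine genes stood at 9 higher and 9 lower of 18 (median 0.04, adjusted p = 0.697), with Cxcl10 at 6.87 ± 1.81 against 4.70 ± 1.30 CPM and Ccl6 at 15.6 ± 4.64 against 23.6 ± 13.8 CPM. The chemokine median was 0.21 without Pax7-CreERT replicate 2, 0.20 without control replicate 3 and -0.0075 without control replicate 1. Of 29 inflammatory cytokine and receptor genes 16 were higher and 13 lower (median 0.02, adjusted p = 0.103). Lif, a cytokine of the IL-6 family, measured 3.18 ± 0.967 against 1.87 ± 0.358 CPM, and Il6st, the receptor subunit it shares with IL-6, 1158 ± 174 against 938.0 ± 129 CPM. The cytokine list passed as lower without Pax7-CreERT replicate 1 (median -0.09, adjusted p = 0.00375) or control replicate 1 (-0.08, 0.0138), while its median was 0.08 without Pax7-CreERT replicate 2 or 3. Adjusted over the list alone, 0 members of these 4 lists passed. With TMM factors the medians of the component, chemokine and cytokine lists were -0.05, -0.04 and -0.07.

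Among leukocyte genes, the neutrophil list was the one that passed. Of 14 neutrophil markers 13 were lower in the Pax7-CreERT mice, with a median log2 fold change of -0.38 (adjusted p = 1.02e-06, and adjusted p = 0.552 with an estimated correlation). No member passed, over the list alone or over all genes. The calcium-binding alarmin gene S100a9 measured 38.3 ± 10.7 against 51.3 ± 5.60 CPM, the myeloid receptor gene Trem1 22.6 ± 5.50 against 31.5 ± 4.68 CPM and the collagenase gene Mmp8 4.66 ± 2.14 against 8.67 ± 3.95 CPM. Pax7-CreERT replicate 2 was lowest (-0.60) and control replicates 2 and 3 were highest (0.37 and 0.44). Control replicate 1 (-0.27) lay below Pax7-CreERT replicates 1 (0.04) and 3 (0.12), so the groups overlapped. The median was -0.07 without Pax7-CreERT replicate 2 and -0.11 without control replicate 3, and the preset-correlation test passed in both (adjusted p = 0.00854 and 0.00728).

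No list of macrophage, monocyte or complement genes passed with all 6 libraries, and some passed, in differing directions, when 1 library was left out. Of 20 macrophage markers 13 were higher and 7 lower (median 0.04, adjusted p = 0.326). The lipoprotein gene Apoe measured 774.5 ± 25.3 against 913.1 ± 162 CPM and the efferocytosis receptor gene Mertk 67.4 ± 1.85 against 60.2 ± 5.28 CPM. This list passed as lower without Pax7-CreERT replicate 1 (median -0.15, adjusted p = 0.00512) or control replicate 1 (-0.21, 0.00416) and as higher without control replicate 3 (0.29, 0.00570). Of 16 tissue-resident macrophage markers 12 were higher (median 0.13, adjusted p = 0.421), with the growth factor gene Igf1 at 105.3 ± 29.8 against 60.5 ± 15.8 CPM and the scavenger receptor gene Stab1 at 36.2 ± 7.68 against 26.3 ± 0.312 CPM. They passed as higher without control replicate 3 (median 0.47, adjusted p = 7.82e-07), while their median was 0.02 without Pax7-CreERT replicate 1 and -0.02 without control replicate 2. Inflammatory monocyte markers were 8 higher and 10 lower of 18 (median -0.03, adjusted p = 0.103). Chil3, a chitinase-like protein of myeloid cells, measured 3.80 ± 1.23 against 7.01 ± 2.26 CPM, and the fibronectin gene Fn1 98.1 ± 46.0 against 54.5 ± 10.1 CPM. The monocyte list passed as lower without Pax7-CreERT replicate 1 (adjusted p = 0.0139), control replicate 1 (0.0206) or control replicate 2 (0.00522), while its median was 0.13 without control replicate 3. Reparative macrophage genes were 11 higher and 7 lower of 18 (median 0.11, adjusted p = 0.292), and passed as lower without Pax7-CreERT replicate 1 (median -0.09, adjusted p = 0.0294). In that list, Lpl, the lipoprotein lipase of fat and muscle, measured 688.0 ± 174 against 1234 ± 262 CPM, and Gpnmb 30.8 ± 11.6 against 56.9 ± 30.6 CPM. Complement genes were 11 higher and 7 lower of 18 (median 0.02, adjusted p = 0.614), with the properdin gene Cfp at 7.38 ± 1.08 against 5.28 ± 1.61 CPM. The complement list was lower without Pax7-CreERT replicate 1 (median -0.11, adjusted p = 0.0216) and higher without control replicate 3 (0.24, 0.00570).

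The lymphocyte, dendritic cell and mast cell lists did not pass. B cell markers stood at 1.21 in Pax7-CreERT replicate 3 and 2.06 in control replicate 3 on the centred log2 scale, and between -1.01 and -0.67 in the other 4 libraries. Of these 12 markers 2 were higher and 10 lower (median -0.28, adjusted p = 0.0732), and Ms4a1, which encodes CD20, measured 9.01 ± 11.9 against 13.7 ± 17.0 CPM. The list passed as lower without Pax7-CreERT replicate 3 (median -0.98, adjusted p = 1.36e-05), control replicate 1 (-0.81, 0.00155) or control replicate 2 (-0.65, 0.00392). Its median was 0.0012 without Pax7-CreERT replicate 1, 0.09 without Pax7-CreERT replicate 2 and 0.65 without control replicate 3 (adjusted p = 0.0609). T and NK cell markers were 7 higher and 3 lower of 10 (median 0.12, adjusted p = 0.694), with Thy1 at 20.3 ± 2.41 against 14.96 ± 3.30 CPM and Foxp3, the regulatory T cell factor, at 4.05 ± 0.525 against 5.16 ± 1.68 CPM. The T and NK cell median was -0.24 without Pax7-CreERT replicate 3, -0.09 without control replicate 1 or 2, 0.32 without Pax7-CreERT replicate 2 and 0.51 without control replicate 3 (adjusted p = 0.0575), and the list passed in none of these fits. Dendritic cell and MHC class II genes were 11 higher and 4 lower of 15 (median 0.19, adjusted p = 0.996). Clec9a, a receptor of cross-presenting dendritic cells, measured 43.1 ± 1.70 against 52.0 ± 3.50 CPM and the transcription factor gene Batf3 1.21 ± 0.159 against 0.395 ± 0.237 CPM. That list passed as higher without control replicate 3 (median 0.77, adjusted p = 1.73e-04), while its median was -0.056 without control replicate 1. Mast cell and eosinophil markers were 8 higher and 1 lower of 9 (median 0.54, adjusted p = 0.103), with the mast cell protease gene Cpa3 at 4.84 ± 2.81 against 3.14 ± 2.84 CPM. They passed as higher without Pax7-CreERT replicate 2 (adjusted p = 5.05e-04) or control replicate 3 (0.00306), while their median was 0.14 without Pax7-CreERT replicate 3, 0.27 without control replicate 1 and 0.31 without control replicate 2.

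Interferon response genes were higher, 23 of 28 members with a median log2 fold change of 0.33 (adjusted p = 0.0359, and adjusted p = 0.777 with an estimated correlation). No member passed, over the list alone or over all genes. The guanylate-binding protein gene Gbp3 measured 158.7 ± 19.7 against 104.8 ± 42.9 CPM, and the antiviral gene Mx2 13.3 ± 3.58 against 8.64 ± 3.43 CPM. Control replicate 3 stood at -0.61 and the other 5 libraries between 0.06 and 0.22. Without control replicate 3 the median was 0.11 (adjusted p = 0.658), and the list also did not pass without Pax7-CreERT replicate 1 (0.0804) or 3 (0.0772). Acute phase and IL-6 to STAT3 genes were 8 higher and 7 lower of 15 (median 0.02, mean -0.07, adjusted p = 0.103), and passed as lower without Pax7-CreERT replicate 1 (median -0.18, adjusted p = 0.00175), while their median was 0.13 without Pax7-CreERT replicate 2. Lrg1, an acute phase glycoprotein also made by endothelium, measured 166.3 ± 11.8 against 202.7 ± 10.3 CPM, and the haptoglobin gene Hp 22.8 ± 4.73 against 34.3 ± 13.2 CPM.

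Relative to the other tested genes, stress genes were higher and hypoxia genes lower with the preset correlation. Of 22 immediate early and dissociation stress genes 21 were higher, with a median log2 fold change of 0.26 (adjusted p = 0.00119, and adjusted p = 0.777 with an estimated correlation). Adjusted over the list alone 3 passed as higher, and over all genes 0 did. These were Hspa1a and Hspa1b (adjusted p = 0.00202 each) and the matricellular gene Ccn1 (587.0 ± 106 against 338.8 ± 102 CPM, adjusted p = 0.0479). The small heat shock gene Hspb1 measured 216.3 ± 19.2 against 163.3 ± 27.3 CPM. This list was lowest in control replicate 3 (-0.47), while Pax7-CreERT replicate 2 (-0.125) lay below control replicates 1 (-0.05) and 2 (0.07). The list did not pass without control replicate 3 (median 0.10, adjusted p = 0.142) or without Pax7-CreERT replicate 3 (adjusted p = 0.0507). Its median was 0.45 without control replicate 2. Of 20 hypoxia and glycolysis genes 14 were lower, with a median of -0.05 (adjusted p = 0.00199, and adjusted p = 0.552 with an estimated correlation). Bnip3 passed as lower adjusted over the list alone (adjusted p = 0.0235), and 0 members passed over all genes. The glucose transporter gene Slc2a1 measured 29.5 ± 3.25 against 37.3 ± 4.55 CPM, and Pdk1, which restrains pyruvate entry into mitochondria, 42.4 ± 2.77 against 49.9 ± 5.32 CPM. The hypoxia list did not pass without Pax7-CreERT replicate 2 (median -0.02, adjusted p = 0.140) or control replicate 2 (median 0.01, adjusted p = 0.0505); its median was -0.15 without Pax7-CreERT replicate 1, -0.09 without control replicate 1 and -0.08 without control replicate 3.

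Muscle atrophy and cachexia genes did not pass as a list, with 19 higher and 8 lower of 27 (median 0.10, adjusted p = 0.529, and median 0.01 with TMM factors). Adjusted over the list alone, 3 members passed as lower. These were Bnip3 (adjusted p = 0.0317), the glucocorticoid-induced transcription factor gene Klf15 at 50.8 ± 3.86 against 82.5 ± 19.0 CPM (0.0464), and Ddit4, an inhibitor of mTORC1 signalling, at 70.0 ± 15.4 against 105.2 ± 9.35 CPM (0.0464). Over all genes none of the 3 passed (adjusted p = 0.891 each). Inhba, which encodes an activin subunit, measured 13.3 ± 0.547 against 9.26 ± 1.86 CPM. The atrophy list passed as lower without Pax7-CreERT replicate 1, relative to other genes, with its own median at 0.03 (adjusted p = 0.0354), while that median was 0.20 without Pax7-CreERT replicate 2. Of 28 nuclear oxidative phosphorylation genes 22 were higher and 6 lower (median 0.14, adjusted p = 0.292), with the succinate dehydrogenase gene Sdha at 67.0 ± 6.34 against 52.9 ± 8.22 CPM and the cytochrome oxidase gene Cox5a at 25.6 ± 0.863 against 20.2 ± 2.34 CPM. The list passed as higher with a filter at 10 CPM (median 0.21, adjusted p = 0.0474).

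Erythroid genes were lower, 13 of 13 members with a median log2 fold change of -0.92 (adjusted p = 1.41e-08, and adjusted p = 0.552 with an estimated correlation). No member passed, over the list alone or over all genes. Epb42, a red cell membrane protein gene, measured 9.15 ± 3.72 against 34.1 ± 28.3 CPM, and Slc4a1, the anion exchanger gene of red cells, 180.2 ± 91.9 against 717.7 ± 857 CPM. Control replicate 3 stood at 1.91 and the other 5 libraries between -1.07 and 0.20. Control replicate 2 (-0.63) lay below Pax7-CreERT replicates 1 (-0.51) and 3 (0.09), so the groups overlapped. The erythroid median was -0.21 without control replicate 3 (adjusted p = 0.00570) and -1.52 without control replicate 2. Cell cycle genes were 8 higher and 11 lower of 19, with a median of -0.04 at an adjusted p of 0.0495, and adjusted p = 0.552 with an estimated correlation. No member passed, over the list alone or over all genes. Mcm6, a subunit of the replicative helicase, measured 12.8 ± 9.60 against 21.6 ± 4.03 CPM and the spindle gene Nusap1 9.48 ± 2.56 against 24.02 ± 18.7 CPM, while the centromeric histone gene Cenpa measured 2.40 ± 0.482 against 1.13 ± 0.182 CPM. The cell cycle list did not pass without Pax7-CreERT replicate 2 (median 0.01, adjusted p = 0.261), control replicate 1 (-0.005, 0.118) or control replicate 3 (-0.11, 0.269), nor with TMM factors (adjusted p = 0.144); its median was -0.03 without Pax7-CreERT replicate 3 and -0.07 without control replicate 2.

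**Figure D2:**
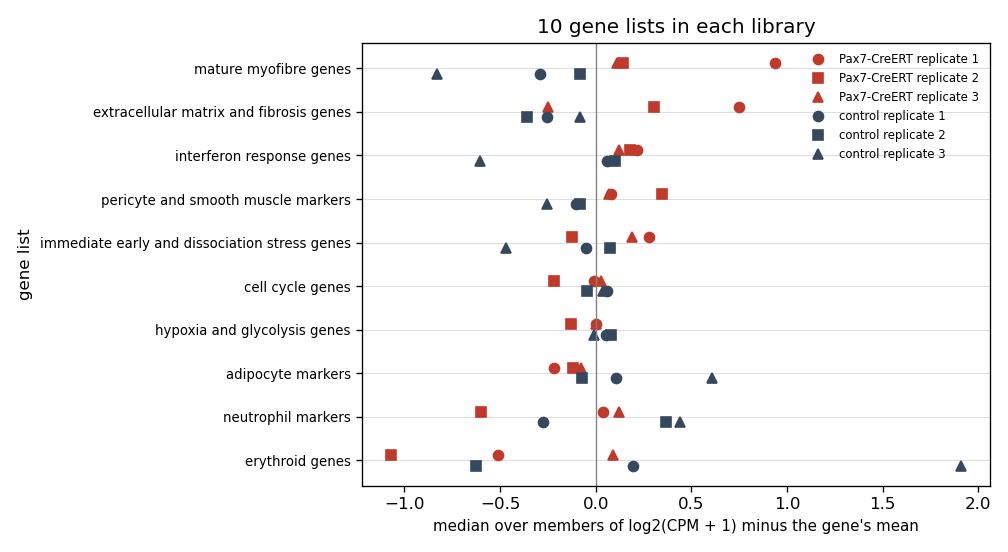
Median over the members of each of the 10 lists of log2(CPM + 1) minus the gene's mean over the 6 libraries, with 1 point per library (red for Pax7-CreERT, dark blue for control; the shape gives the replicate). The mature myofibre genes lie between 0.11 and 0.94 in the Pax7-CreERT libraries and between -0.83 and -0.08 in the controls, and control replicate 3 lies apart for the erythroid (1.91), adipocyte (0.61) and interferon (-0.61) lists.

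In 13 of the 22 lists that did not pass, the test pointed lower while the median of the members was above 0: NF-kB components, chemokines, cytokines and receptors, satellite cell, macrophage, reparative macrophage, T and NK cell, dendritic cell, fibro-adipogenic progenitor, endothelial, atrophy, acute phase and complement genes. The mean was below 0 for the endothelial (-0.005) and acute phase (-0.07) lists among them. For some of these lists a median below that of all genes (0.09) does not account for the direction. The medians were 0.19 for dendritic cell, 0.12 for T and NK cell and for progenitor, 0.11 for reparative macrophage and 0.10 for atrophy genes. The direction of a list that did not pass carries little weight. Leaving out control replicate 3 gave 14 lists past the threshold, 7 of them among the 10, and leaving out Pax7-CreERT replicate 1 gave 17.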

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

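The voom fit, the filter at 10 CPM, removal of erythroid genes, the comparison of 2 against 2 libraries and the thinning of haemoglobin genes were chosen after the data were seen, and the other alternatives were planned. No gene passed as higher in any alternative. Genes passing as lower numbered 2 with no filter and with voom (Zfp433 and Zfp697) and 2 in the comparison of 2 against 2 (Prom1 and Zfp697), 0 to 1 when each library was left out in turn, and 1 in the other alternatives. The fits without 1 library have fewer samples; otherwise the cause was not tested. Ikbkb passed in none, with log2 fold changes from -0.13 with TMM factors to 0.02 without control replicate 2. Lists past the threshold numbered 0 with an estimated correlation and 0 with fry, 10 to 17 when each library was left out, and 8 to 13 otherwise; genes that vary together widen the first 2 tests by their construction. When each library was left out, the medians ran from -0.21 to 0.29 for macrophage genes, from -0.056 to 0.77 for dendritic cell and MHC class II genes and from -0.12 to 0.24 for complement genes, each lowest without control replicate 1 and highest, and past the threshold, without control replicate 3. With 2 against 2 libraries the B cell (median 0.90) and dendritic cell and MHC class II lists (0.80) passed as higher, where the test with all libraries pointed lower. For the dendritic cell list that direction carried little weight, since its median was 0.19 with all libraries (camera adjusted p = 0.996). The interferon list pointed lower there without passing (adjusted p = 0.935), although its median was 0.11. For these lists the cause was not tested. The interferon list also failed to pass with a constant of 0.25 (adjusted p = 0.0534) and with array weights (0.295), and the immediate early list with array weights (0.109) and 2 against 2 (0.551). Of the lists that did not pass with all libraries, some passed under other settings that kept every library: tissue-resident macrophage, mast cell, endothelial and tenocyte markers with array weights, Schwann cell markers with a constant of 5, no filter or voom, B cell markers with a constant of 5 or voom, commitment and acute phase genes with no filter, cytokine, reparative macrophage and oxidative phosphorylation genes with a filter at 10 CPM, and atrophy genes with a filter at 50 CPM. The cell cycle list passed in 8 of 20 alternatives, the mature myofibre and pericyte lists in 19 of 21. Signs differed from those with all libraries, called or not, in 27 of 2138 gene values and 73 of 659 list directions. The count-based tests planned for whole reads were not run, because whole reads were not recovered. Depth limits genes near 1 CPM, where counting error alone had an SD of up to 49.7%.

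Over all 10 ways to divide the 6 libraries into groups of 3, 3 gave as many genes as the real division (1 gene, highest other 2) and 8 gave as many lists (10 lists, highest other 20). So few divisions cannot give a share under 0.05, but that limit does not account for these counts. With 8 of 10 divisions giving at least 10 lists, the real one included, the number of lists called did not set the genotype apart. The same held for the number of genes, with 3 of 10 divisions. Other divisions called as many as 20 lists. A structure of the libraries that does not follow the genotype and a preset correlation too small for genes that vary together were not told apart.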

Other observations

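The test of haemoglobin dilution was set before its result, though after the libraries had been compared, and the other tests here were chosen after the result was seen, as were the marker genes whose levels open this part.

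The mononuclear cell preparation was rich in vascular transcripts. Over the 6 libraries, endothelial markers had a median level of 384.5 ± 35.7 CPM and pericyte and smooth muscle markers one of 252.1 ± 27.2 CPM (SD, n = 6), against 28.0 ± 7.06 CPM for macrophage markers, 4.97 ± 2.27 CPM for neutrophil markers and 1.14 ± 0.684 CPM for T and NK cell markers. The pericyte gene Rgs5 measured 6923 ± 1093 CPM, and the endothelial genes Pecam1 and Flt1 2169 ± 254 and 1899 ± 394 CPM. The macrophage receptor genes Csf1r and Adgre1 measured 27.4 ± 8.44 and 3.94 ± 0.898 CPM, the pan-leukocyte gene Ptprc (CD45) 40.3 ± 11.7 CPM and the myeloid lysozyme gene Lyz2 331.9 ± 113 CPM. Satellite cell markers had a median of 54.5 ± 4.37 CPM and fibro-adipogenic progenitor markers one of 107.0 ± 24.7 CPM, with Pdgfra at 185.7 ± 71.0 CPM. The satellite cell list holds Notch3, which mural cells also express (means of 282.0 CPM in Pax7-CreERT mice and 231.9 CPM in controls). Pax7 itself had means of 16.7 and 16.3 CPM, so the level of this list does not measure satellite cells. Schwann cell and neural markers had a median of 74.6 ± 6.09 CPM. Genes of mature fibres were present too, with Acta1, the skeletal actin gene, at 191.3 ± 111 CPM and Myh4, a fast myosin gene, at 130.5 ± 58.5 CPM. Levels compare transcripts, not cell numbers, and leukocyte genes at a few CPM rest on few reads.

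The heat shock genes Hspa1a, Hspa1b, Hspa1l and Hsph1 were higher in the Pax7-CreERT mice without passing the adjustment over all genes. Reads divided differently between the near-identical Hspa1a and Hspa1b would raise 1 of them and lower the other, while both were higher (log2 fold change 1.23 and 1.40). Their summed CPM had a log2 fold change of 1.30 (SE 0.24). It had to be higher once both genes were, so it adds nothing to them. The adjacent Hspa1l, from 18.75 CPM in control replicate 3 to 65.8 CPM in Pax7-CreERT replicate 1, ranked the libraries in the same order as Hspa1a. Division of reads between Hspa1l and its neighbours was not tested, so the chromosome 17 genes may not be separate observations. The median of the 4 genes was 1.05 without control replicate 3, so the difference in them did not rest on that library alone. The genes were named on the condition that the groups did not overlap, so some difference without it was fixed in advance. Dissociation stress stays open: the largest log2 fold change of 8 immediate early genes was 0.51 (0.24 without control replicate 3), but the 4 heat shock genes were picked for their small p-values, and in the fixed stress list Hspb1 stood at 0.41 and Ccn1 at 0.82. An effect of the genotype also stays open, untested.

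The mature myofibre genes were higher in the Pax7-CreERT mice, all 24 of them. Without Pax7-CreERT replicate 1 and control replicate 3 the median log2 fold change was 0.35, with 22 of 24 higher; these were the highest and lowest libraries for this list, so leaving them out narrows the difference by construction. Dilution by haemoglobin reads is argued against, since the median was 0.77 with erythroid genes removed and the libraries rescaled. Carry-over of fibre fragments into the preparation is a candidate explanation, as the commitment and differentiation list had a median of 0.12. A difference in the muscle itself stays open, untested.

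Zfp697 was lower in every Pax7-CreERT library. A fall over the region is argued against, since the 12 tested genes within 1000 kb had a median log2 fold change of 0.28 (SD 0.29, lowest -0.60 for Hsd3b4). Zfp697 lies on chromosome 3, Pax7 on chromosome 4 and Ikbkb on chromosome 8, so a passenger segment around Pax7 or Ikbkb would not hold it. A sequence variant or segment elsewhere that differs between the 2 genotypes and an effect of the deletion stay open, and neither was tested.

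Zfp433 (chromosome 10, 81704825 to 81881086) measured 0.0852 ± 0.0427 CPM against 3.16 ± 0.182 CPM in the controls (SD, n = 3 each, adjusted p = 0.158). The overlapping Gm32687 measured 8.41 ± 1.36 against 3.53 ± 1.86 CPM, and the summed CPM had a log2 fold change of 0.32 (SE 0.24), so reads of this locus may have been assigned to Gm32687 in the Pax7-CreERT libraries. Prom1, named because it passed in 1 alternative, measured 61.5 ± 9.58 against 103.2 ± 41.8 CPM (log2 fold change -0.65, adjusted p = 0.896). Control replicate 3 was at 55.0 CPM and the other controls at 124.2 and 130.3 CPM. Without it the log2 fold change of Prom1 was -1.05 (adjusted p = 0.0807), and the adjusted p ran from 0.0433 to 0.999 over the alternatives.

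Tsc22d3, a gene induced by glucocorticoids, measured 549.5 ± 80.6 against 863.1 ± 81.1 CPM (adjusted p = 0.891), and a lower glucocorticoid response in the Pax7-CreERT mice might be one reading. In a list of 24 other glucocorticoid-induced genes, written after Tsc22d3 was noticed, camera gave p = 2.575e-05 toward lower values with the preset correlation and p = 0.0664 with an estimated one, with 13 of the 24 lower and a median log2 fold change of -0.05 (-0.14 without control replicate 3), which leaves the question undecided.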
